A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

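NET-seq was done on 5 budding yeast samples, labelled as 3 WT and 2 rpa190-F1205H. Per the labels' protocols, cells grown in rich medium were collected by filtration and ground frozen, RNA polymerase I complexes were precipitated through HA-tagged Rpa135, and the 3′ ends of the bound RNA were joined to a DNA linker, copied into cDNA, circularised and amplified. The deposited values are raw counts of RNA 3′ ends at each nucleotide and strand of 1 rDNA repeat of 9137 nt (chromosome XII 458433 to 467569), as judged from the values: they are whole numbers, and the 2 highest positions in each genotype are the last nucleotides of 5.8S and 25S. Per the submitters' processing notes the tools were bcl2fastq 2.18.0.012, Trim Galore 0.4.1, BWA 0.6 and SAMtools 1.3.1. Their settings, the genome build, the handling of reads shared by the rDNA repeats, and the treatment of duplicates or molecular identifiers are not given in the sources used here. The rDNA repeats are nearly identical and the files hold 1 of them, so signal could not be assigned to a single repeat.

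Groups were taken from the genotype label of each sample. Inside the 2 files labelled as the mutant the sample column reads WT 1 and WT 2, and the titles of these samples write the substitution differently from the genotype label. RPA190 lies outside the measured region, so that the genotype could not be checked from the counts. The labels do not say whether the samples of a group came from separate cultures, and the p-values then measure only the spread between these samples, which may be technical. The labels give no batch. Libraries of a genotype differed by more than sampling noise (chi-square per degree of freedom 1.58, 2.73 and 2.44 among WT pairs and 4.54 for the mutant pair), so none was treated as a repeat deposit of another. This does not show that they came from separate cultures.

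The 35S gene was taken as nt 1 to 6858 of the repeat (chromosome XII 460712 to 467569), with the region bounds as the files give them. They equal those of the genes RDN37-2, ETS1-2, RDN18-2, ITS1-2, RDN58-2, ITS2-2, RDN25-2 and ETS2-2 in the table of RefSeq genes. A0 was placed 90 nt before the 18S 5′ end, A2 at nt 212 of ITS1 and C2 at nt 138 of ITS2. Sense 35S totals were 519517, 445251 and 465427 counts in WT, and 1861226 and 301306 in the mutant. A count of 0 allows a share of up to 5.77e-04%, 6.74e-04% and 6.45e-04% in the WT libraries, and 1.61e-04% and 9.96e-04% in the mutant libraries (3 counts of the total). Floors and intervals cover counting error only.

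Counts per position and per 100 nt window were compared with edgeR 4.0.16 (quasi-likelihood test, TMM factors, library size the 35S total, filterByExpr, no block, Benjamini-Hochberg threshold 0.05) in R 4.3.3. Positive log2 fold changes are higher in the mutant, and their SE was approximated as the size of the log2 fold change divided by the square root of the F statistic. Windows of each region were tested as sets with fry of limma 3.58.1. Shares, pause counts and the Gini coefficient were compared by two-sided exact permutation tests in SciPy 1.17.1 with Python 3.11.15, which for 10 splits cannot go below 0.2. Unevenness and pause sites were measured after thinning each library to 301306 counts, with the same draws and total kept when a library was left out. The fold change by last base was set against 1000 circular shifts of the profile. On simulated counts for 6858 positions, with 200 changed and the sizes of these 5 libraries, the position test recovered 32% of 2-fold and 92% of 4-fold changes, and 0.8% of its calls were false. The changes went both ways at better-covered positions, with a set dispersion of 0.05. In the real libraries 4126 of 5990 tested positions were called, so these rates do not carry over to the real calls. The pause caller, tested on simulated data with 150 planted sites, recovered 100% of them with 0 false sites. Those sites were high peaks of equal height on an even background with counting noise only. The real profiles are more uneven, so this does not measure how well the caller works on them.

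Named positions were the 10 with the largest and the 10 with the smallest log2 fold change among those past the threshold whose libraries did not overlap between genotypes, which left 4026 of 4126. Named windows were the 5 highest and the 5 lowest past the threshold. The 5 positions of highest mean share in each genotype, all 7 regions and the cleavage sites were named as well. These rules, the tests and most alternatives were fixed before the data were examined. Alternatives covered the scaling (DESeq2 1.42.0 size factors, the 35S total, spacer counts without positions within 10 nt of a mature 3′ end), the DESeq2 test, the filter, the mature 3′ ends, a ceiling at the 99th percentile, the pause definition, the window size, the base offset, the random draw of the thinning and each library left out. Shares, ratios and bases among the spacers alone were taken without the first 50 nt past each mature 3′ end. For shares and ratios, 0 to 100 nt in steps of 5 were left out instead.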

Results

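Native elongating transcript sequencing (NET-seq) is meant to map the RNA 3′ ends that are held in elongating polymerases. Such an end marks the last nucleotide a polymerase had added when the cells were harvested. Ends of finished rRNA were captured here as well, as the mature 3′ ends of 5.8S and 25S below show. RNA polymerase I, the enzyme that transcribes the 35S precursor of 18S, 5.8S and 25S rRNA, was captured from budding yeast through its HA-tagged second-largest subunit, Rpa135. There were 3 wild-type (WT) libraries and 2 libraries of the rpa190-F1205H strain, which carries a substitution in the trigger loop of Rpa190, the largest and catalytic subunit. The 35S gene held 519517, 445251 and 465427 sense-strand 3′ ends in the WT libraries, and 1861226 and 301306 in the mutant libraries. The median count per nucleotide was 26, 22 and 25 in WT, and 145 and 25 in the mutant. The gene spans chromosome XII from 460712 to 467569 and is transcribed toward the lower coordinates, and nucleotides are numbered here from 1 to 6858 from its 5′ end. Inside both files labelled as the mutant, the column that names the sample reads WT 1 and WT 2, so the genotype of these 2 libraries rests on the sample labels. The data hold no other value that checks the label, because the RPA190 gene itself was not measured.

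The distribution of 3′ ends along the gene differed between the genotypes far more than between libraries of one genotype. Across the 6858 nucleotides, Spearman's rho was 0.965 to 0.971 among the WT libraries and 0.939 between the mutant libraries, but only 0.606 to 0.642 between a WT and a mutant library. These correlations run across positions, which are not independent replicates. In both genotypes the 2 highest positions were the last nucleotides of 5.8S and 25S. The last nucleotide of 5.8S (nt 3019) held 15.7% ± 0.793 of the sense signal in WT (SD, n = 3) and 5.98% ± 0.0824 in the mutant (SD, n = 2). The last nucleotide of 25S (nt 6647) held 14.0% ± 1.08 and 6.09% ± 0.652, and that of 18S (nt 2500) held 1.71% ± 0.162 and 0.795% ± 0.107. These and 2 others were the 5 highest positions in both genotypes, though not in the same order. At nt 3018 in 5.8S the shares were 1.34% ± 0.190 in WT and 0.817% ± 0.202 in the mutant, and at nt 6409 in 25S they were 1.16% ± 0.377 and 1.09% ± 0.254. 5S rRNA, which RNA polymerase III makes from the other strand of the repeat, took 5.32% ± 0.503 of all counts in WT and 2.73% ± 0.291 in the mutant, and all counts outside the sense strand of the 35S gene took 5.42% ± 0.503 and 2.90% ± 0.277. With 3 libraries against 2 there are 10 splits, and the smallest two-sided p of an exact permutation test is 0.2. That value was reached by the differences between regions, landmarks, bases, pause sites and measures of unevenness as first measured, unless another p stands beside them. It does not extend to values recomputed under another setting or with a library left out. Shares at nt 3018 and nt 6409 were not tested.

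The first question was whether the mutant polymerase was distributed differently over the parts of the gene. The 5′ external transcribed spacer (5′ ETS, nt 1 to 700) held 2.94% ± 0.0300 of the sense 35S signal in WT (SD, n = 3) and 9.61% ± 1.04 in the mutant (SD, n = 2), which was 3.27 times as much. Internal transcribed spacer 1 (ITS1, nt 2501 to 2861) held 0.742% ± 0.00961 in WT and 1.88% ± 0.153 in the mutant, and ITS2 (nt 3020 to 3251) held 1.52% ± 0.0836 and 2.06% ± 0.166. The 3′ ETS (nt 6648 to 6858) held 0.465% ± 0.0207 and 0.517% ± 0.0182. The mutant share was lower in 5.8S (8.89% ± 0.169 against 19.5% ± 0.816) and in 25S (51.6% ± 1.80 against 53.7% ± 0.454). Most of the 5.8S difference of -10.7 percentage points lay at its 3′ end, since it was -1.20 points when positions within 5 nt of the mature 3′ ends were left out (2.23% ± 0.0481 against 3.43% ± 0.0721) and -1.13 with counts capped at each library's 99th percentile. In 18S it was 25.4% ± 0.598 against 21.1% ± 0.988, but this difference of 4.33 percentage points turned to -0.693 without those positions and to -0.887 with the same ceiling (exact permutation p = 0.4 for each). The 25S difference of -2.06 points was -6.99 without the mature 3′ ends, -0.786 without mutant library 1 and -3.33 without mutant library 2. Leaving those ends out did not turn the direction in the 5′ ETS (11.2% ± 1.12 against 4.47% ± 0.132). Among spacer counts alone, with the first 50 nt past the 3′ ends of 18S, 5.8S and 25S left out, the 5′ ETS held 74.0% ± 0.470 in the mutant and 69.6% ± 0.252 in WT. On this footing the mutant share was lower in ITS1 (13.1% ± 0.263 against 15.4% ± 0.244), ITS2 (11.8% ± 0.169 against 13.0% ± 0.447) and the 3′ ETS (1.14% ± 0.0375 against 1.97% ± 0.101). These values depend on the stretch left out, a choice made after the data were seen. With none left out the 5′ ETS held 68.3% ± 0.701 against 51.9% ± 0.687 and ITS1 13.4% ± 0.219 against 13.1% ± 0.437 (exact permutation p = 0.6 for ITS1). With 30 nt left out the 3′ ETS held 2.38% ± 0.0719 against 2.39% ± 0.0866 (exact permutation p = 1.0). The exact permutation p was 0.2 for each of the 7 regions, also after Benjamini-Hochberg adjustment over them.

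**Figure D1:**
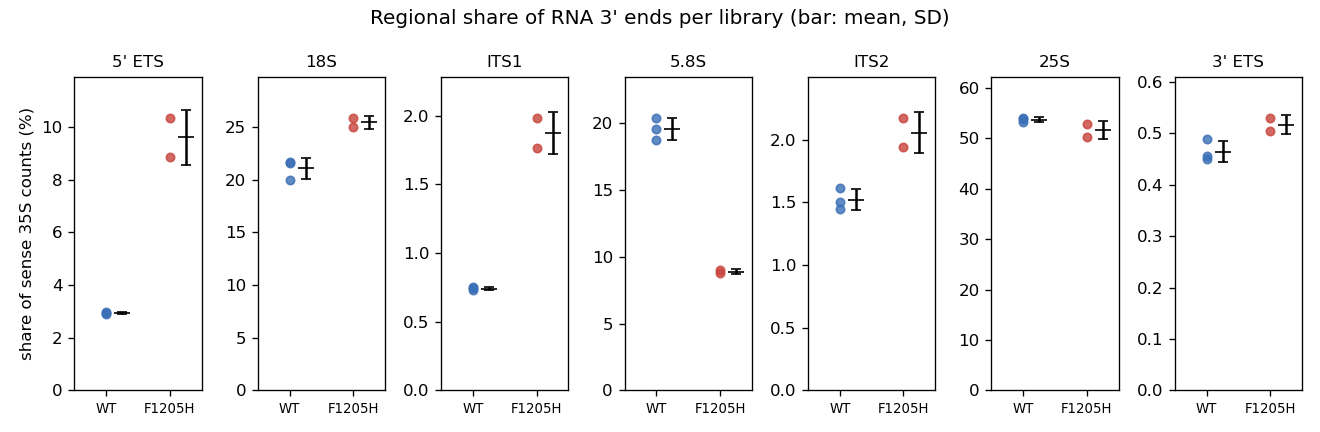
Share of sense-strand 35S counts (%, linear axes from 0) in each of the 7 regions of the gene, 1 point per library, for WT (n = 3) and rpa190-F1205H (n = 2), with the mean and SD beside the points. The 5′ ETS mean is 2.94% in WT and 9.61% in the mutant, and the 5.8S mean is 19.5% and 8.89%.

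Over the first 1000 nt of the gene, the share of signal was 6.57% ± 0.381 in WT and 13.2% ± 1.06 in the mutant. In windows of 100 nt, tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 29 of 69 windows were higher and 27 lower in the mutant at an adjusted p below 0.05. This split depends on TMM scaling. Scaled to the 35S total, 39 windows were higher and 9 lower, and scaled to spacer counts, 3 and 60. The 5 windows that rose most included the first 4 of the gene. From the 5′ end on, these 4 windows rose by 1.68 ± 0.0726 (log2 fold change, SE), 1.60 ± 0.121, 1.56 ± 0.0805 and 1.24 ± 0.0599. The remaining window, nt 5201 to 5300, lies in 25S and rose by 1.301 ± 0.0567. The 5 that fell most were the windows with the 3′ ends of 5.8S (nt 3001 to 3100, -1.56 ± 0.0789), 25S (nt 6601 to 6700, -1.43 ± 0.115) and 18S (nt 2401 to 2500, -0.83 ± 0.0943), and windows nt 6101 to 6200 (-0.96 ± 0.0385) and nt 5401 to 5500 (-0.83 ± 0.0737) inside 25S. With the mature 3′ ends left out, the window of the 5.8S 3′ end was higher in the mutant instead (log2 fold change 0.22), that of the 25S 3′ end was at -0.22 in place of -1.43 (adjusted p = 0.00635 with edgeR), and that of the 18S 3′ end no longer passed (adjusted p = 0.246 with edgeR).

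As a set, the 7 windows of the 5′ ETS rose (median log2 fold change 1.24, adjusted p = 7.53e-04 with limma's fry) and so did the 4 windows of ITS1 (0.93, adjusted p = 7.53e-04) and the first 10 windows of the gene (1.22, adjusted p = 8.31e-04). The 33 windows of 25S fell (median -0.19, adjusted p = 0.0338 with fry), as did the single window centred in 5.8S (-0.70, adjusted p = 7.53e-04). Fry gave no call for the 18 windows of 18S (median -0.07, test direction up, adjusted p = 0.504), the 3 windows of ITS2 (median 0.15, test direction down, adjusted p = 0.263) or the 3 windows of the 3′ ETS (median 0.49, test direction down, adjusted p = 0.128). In these last lists the median and the test differ in sign, and a window of ITS2 and a window of the 3′ ETS hold the end of 5.8S or 25S. These log2 fold changes are relative to TMM scaling, under which the median position lay at 0.06. Scaled to the 35S total alone the median position lay at 0.48, and scaled to spacer counts alone at -1.32. Scaled to spacer counts, where the 5′ ETS itself makes up most of the total, the 5′ ETS windows had a median of -0.0331 (test direction up). Window nt 301 to 400 lay at -0.0341. The windows of ITS1 (median -0.34) and the first 10 windows of the gene (-0.0476) turned to lower (adjusted p = 0.00203 and 0.00363 with fry). The first 3 windows of the gene then lay at 0.41, 0.32 and 0.28, and window nt 5201 to 5300 at 0.0337, where it no longer passed (adjusted p = 0.711 with edgeR). Scaled to the 35S total, 18S and 25S were higher in the mutant (medians 0.26 and 0.14, adjusted p = 0.00806 and 0.00668 with fry). So were ITS2 and the 3′ ETS (0.48 and 0.82, adjusted p = 0.00806 and 0.0251 with fry). Scaled to spacer counts, 18S, ITS2 and the 3′ ETS were lower instead (medians -1.34, -1.12 and -0.77, adjusted p = 0.00117, 6.44e-04 and 6.30e-04 with fry).

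**Figure D2:**
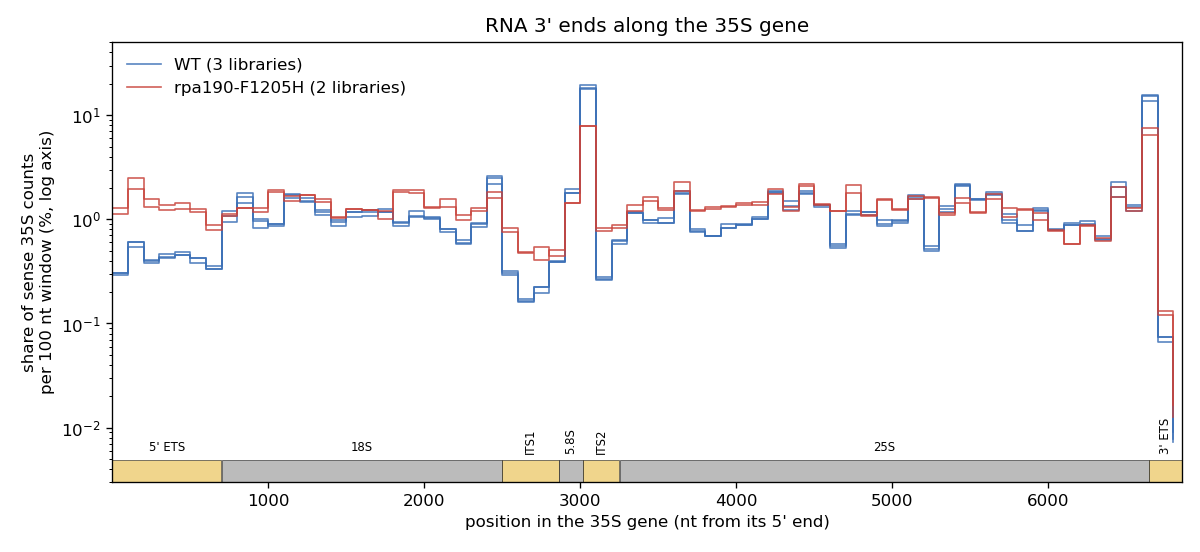
Share of sense-strand 35S counts per 100 nt window (%, log axis; the last window holds 58 nt) against the position in the gene (nt from its 5′ end), 1 line per library, with the regions of the gene drawn to scale under the lines. Both mutant lines lie above all 3 WT lines over the 5′ ETS, where the whole region holds 9.61% against 2.94%, and below them at the windows with the 3′ ends of 5.8S and 25S.

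At the level of single nucleotides, 4126 of 5990 tested positions differed in edgeR's quasi-likelihood test at an adjusted p below 0.05, 2158 of them higher and 1968 lower in the mutant. The higher positions were 52.3% of the calls under TMM scaling, 69.0% when scaled to the 35S total and 16.1% when scaled to spacer counts. In the 5′ ETS 370 of 474 tested positions rose and 11 fell, in ITS1 102 of 168 rose and 12 fell, and in ITS2 99 of 156 rose and 9 fell. In 18S 548 of 1729 rose and 619 fell, in 25S 986 of 3271 rose and 1229 fell, and in 5.8S 30 of 141 rose and 71 fell. In the 3′ ETS 23 of 51 rose and 17 fell.

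Of the 10 positions that rose most among those whose libraries did not overlap between genotypes, 9 were G, and 4 lay in the 5′ ETS, 4 in 18S, 1 in ITS2 and 1 in 25S. Position nt 3134 (G, ITS2, chromosome XII 464436) had 135 and 28 counts in the mutant libraries and none in the WT libraries, which made it at least 27.2-fold higher, against a floor of 3 counts over the WT group. On the same footing nt 182 (G, 5′ ETS) was at least 22.5-fold higher, nt 45 (A, 5′ ETS) at least 20.5-fold, nt 1360 (G, 18S) at least 19.8-fold, nt 556 (G, 5′ ETS) at least 13.8-fold, nt 6456 (G, 25S) at least 13.5-fold and nt 496 (G, 5′ ETS) at least 11.5-fold. The other 3, all G in 18S, had 1 WT count in all, with ratios of 233 at nt 2492 (95% counting interval 41.7 to 9241), 212.5 at nt 1971 (37.9 to 8412) and 133 at nt 1814 (23.7 to 5272). At each of the 3 that count was in WT library 3. With each library left out, log2 fold changes ran from 6.98 to 10.2 at nt 2492 and nt 1971. At nt 1814 they ran from 6.41 to 9.61. Intervals and floors cover counting error only. All ratios and floors here are under TMM scaling, and another scaling would move them.

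None of the 10 positions that fell most was a G, and 6 of them lay in the 3′ ETS between nt 6657 and 6662, just past the 25S 3′ end. There nt 6657 (C) changed by -3.82 ± 0.461 (log2 fold change, SE), nt 6659 (U) by -3.70 ± 0.433, nt 6661 (C) by -3.68 ± 0.273, nt 6662 (U) by -3.27 ± 0.244, nt 6658 (U) by -3.26 ± 0.430 and nt 6660 (U) by -3.24 ± 0.373. At nt 6660 the mutant libraries held 25 and 2 counts, and the change ran from -4.12 to -2.97 when each library was left out. At nt 6662 the CPM values were 607 ± 62.3 in WT (SD, n = 3) and 64.0 ± 5.08 in the mutant (SD, n = 2). In 25S the positions were nt 6025 (C, -3.49 ± 0.353), nt 6147 (A, -3.17 ± 0.247) and nt 6027 (C, -3.16 ± 0.242), and in ITS1 nt 2712 (C, -3.19 ± 0.369), which is at the A2 site where the 20S precursor of 18S is cut from the transcript.

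Around the sites where the precursor is cut, the counts within 25 nt were set side by side. The mutant share was 3.09 times that of WT around C2 in ITS2 (0.542% ± 0.0464 against 0.175% ± 0.00549), 2.77 times around the 5′ end of 25S (0.383% ± 0.0445 against 0.138% ± 0.00461), 1.94 times around A1, the 5′ end of 18S (0.259% ± 0.00946 against 0.134% ± 0.00823), and 1.92 times around A0 in the 5′ ETS (0.489% ± 0.0429 against 0.255% ± 0.0151). It was 1.301 times that of WT around the 5′ end of 5.8S (0.227% ± 0.0177 against 0.175% ± 0.00908) and 1.20 times around A2 (0.157% ± 0.00788 against 0.131% ± 0.0167). Around the mature 3′ ends it was 0.630 times for 18S (site D), 0.407 times for 5.8S and 0.447 times for 25S. The rises around A0 and A2 were smaller than those of the whole 5′ ETS and the whole ITS1 given above. The rise around C2 was larger than that of the whole ITS2. Calls at single positions followed the share at some sites and not at others. Around C2, 26 of 36 tested positions rose and none fell, around the 25S 5′ end 24 of 33 rose and none fell, and around A0 15 of 24 rose and 3 fell. Around A1 9 of 17 rose and 2 fell, and around the 5.8S 5′ end 9 of 24 rose and 5 fell. Around A2 7 of 21 rose and 8 fell, although the share was higher in the mutant. Around the 18S 3′ end 19 of 35 rose and 5 fell, although the share was lower, around the 5.8S 3′ end 15 of 42 rose and 17 fell, and around the 25S 3′ end 2 of 43 rose and 29 fell.

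The second question was whether RNA 3′ ends lay at other sequences in the mutant. The clearest difference was at G. It was the last base of 6.75% ± 0.396 of the sense 35S signal in WT (SD, n = 3) and 20.8% ± 0.994 in the mutant (SD, n = 2), while G makes up 26.3% of the gene. U ended 53.2% ± 1.51 of the signal in WT and 40.9% ± 0.757 in the mutant. For A the shares were 25.3% ± 1.47 and 22.6% ± 2.80, and for C 14.7% ± 0.387 and 15.7% ± 1.05 (exact permutation p = 0.4 for each). The difference at A was -2.76 percentage points over both mutant libraries, -0.785 without mutant library 1 and -4.74 without mutant library 2, and that at C was 1.05, 0.306 and 1.78 in the same order. The Benjamini-Hochberg adjusted p over the 4 bases was 0.4 for each (exact permutation test). The last nucleotides of 5.8S and 25S are U, and without the mature 3′ ends the difference at U was -0.528 percentage points in place of -12.3 (exact permutation p = 0.6), while that at A was -10.4, that at C -3.07 and that at G 14.0. In the 5′ ETS alone, which holds no mature rRNA, G ended 9.67% ± 0.984 of the signal in WT and 23.0% ± 0.330 in the mutant. Among 3′ ends inside 5S rRNA, without its last 6 nt, the share at G was 24.1% ± 0.538 in WT and 26.7% ± 1.00 in the mutant.

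**Figure D3:**
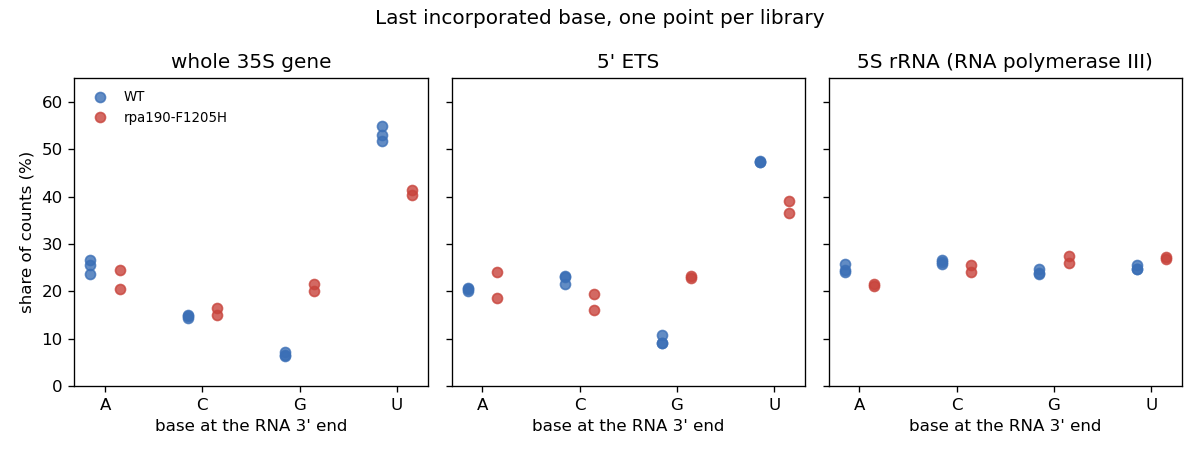
Share of counts (%) by the base at the RNA 3′ end, 1 point per library (3 WT, 2 rpa190-F1205H), over the whole 35S gene, the 5′ ETS and 5S rRNA, the last made by RNA polymerase III. At G the mutant mean is 20.8% against 6.75% in WT over the 35S gene and 23.0% against 9.67% in the 5′ ETS, but 26.7% against 24.1% in 5S.

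Position by position, 1133 of 1576 tested G positions rose and 45 fell. At A, 336 of 1616 positions rose and 827 fell, at C 248 of 1114 rose and 493 fell, and at U 441 of 1684 rose and 603 fell. The mean log2 fold change was 1.69 at G, -0.33 at A, -0.30 at C and -0.05 at U. Positions at G lay 1.91 above those at the other bases, against an SD of 0.0531 over 1000 circular shifts of the sequence along the gene. The same difference from the other bases was -0.84 at A, -0.72 at C and -0.47 at U. The adjusted p was 0.001 for each base, the smallest that 1000 shifts can give. This permutation describes these 5 libraries, since positions are not replicates of a genotype. The order of G over the other bases does not depend on the scaling, which moves all positions of a library alike. The numbers of calls and the mean at each base do depend on it, and those here are under TMM scaling. Scaled to spacer counts, only 695 of 5480 tested positions were higher over all bases.

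Pause sites were called in each library, thinned to 301306 counts, as positions with at least 10 counts that exceeded the mean of the 100 nt on each side by more than 3 SD. There were 126 ± 3.06 sites per WT library (SD, n = 3) and 144 ± 8.49 per mutant library (SD, n = 2). The mature 3′ ends took more of the thinned total in WT, so that the depth over the rest of the gene was not matched. The difference of 17.7 sites was 11.7 without mutant library 1. Over 100 other random draws of the thinned counts, chosen after the data were seen, it was 15.1 on average and ranged from 10.0 to 22.8. The order was not kept under other definitions: the difference became -0.833 with a threshold of 4 SD (exact permutation p = 1.0), and -40.5 with a threshold set by the median and the median absolute deviation (p = 0.6 in the same exact test). It was 0 with 200 nt on each side (p = 1.0, exact) and 5.5 with the ceiling at the 99th percentile (p = 0.6, exact). The sites themselves differed more between than within genotypes. A WT library shared 75.7% of its sites with another WT library on average, the mutant libraries shared 58.4%, and libraries of different genotype shared 28.3%. There were 19 sites found in all 5 libraries, 55 in both mutant libraries and no WT library, and 42 in all 3 WT libraries and no mutant library. Over the 100 other draws the sites of the mutant alone were 51.4 on average (45 to 55). Those of WT alone were 47.4 (41 to 53), so the draw used here overstates the imbalance.

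G was the last base of 11.1% ± 1.31 of the pause sites in the mutant and of 0.792% ± 0.0193 in WT, where each library had a single such site. A was the last base of 16.3% ± 11.8 in the mutant and 42.0% ± 5.38 in WT, and U of 51.7% ± 11.7 and 35.8% ± 5.51. For C the values were 20.9% ± 1.23 and 21.4% ± 0.792 (exact permutation p = 0.6). The adjusted p over the 4 bases was 0.267 for A, G and U (exact permutation test). The mutant libraries differed from each other in these shares, with A at 8.0% and 24.6% of the sites and U at 60.0% and 43.5%, and the difference at U was 15.9 percentage points over both, 7.68 without mutant library 1 and 24.2 without mutant library 2. Of the 55 sites of the mutant alone, 7 ended in G, 4 in A, 12 in C and 32 in U. Of the 42 sites of WT alone, none ended in G, 25 in A, 9 in C and 8 in U. By region, 15 of the 55 sites lay in 18S and 27 in 25S, and 10 and 27 of the 42. There, 3′ ends of finished or broken rRNA cannot be told from those held in a polymerase. Over the 9 nt of RNA ending at the pause site, the length of the RNA:DNA hybrid, purines made up 57.8% ± 0.139 in the mutant and 50.2% ± 1.43 in WT.

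Unevenness of the profile was lower in the mutant with each library thinned to the same 35S total. The mature 3′ ends took more of that total in WT, so the depth over the rest of the gene was not matched. The Gini coefficient over the 6858 positions was 0.735 ± 0.00868 in WT (SD, n = 3) and 0.592 ± 0.0130 in the mutant (SD, n = 2). The highest 1% of positions held 40.0% ± 1.61 of the signal in WT and 21.1% ± 0.427 in the mutant, and the mature rRNA 3′ ends are among them. With these ends left out before thinning, the difference in the Gini coefficient was -0.0731 in place of -0.142.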

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

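Of the values in this part, those per 1000 spacer counts were chosen only after the result was seen. Counts outside the sense strand of the 35S gene were low, and 5 kinds took a larger share of all counts in the mutant than in WT, while others took a smaller one. The strand opposite the 35S gene held 0.110% ± 0.00819 of all counts in the mutant (SD, n = 2) and 0.0602% ± 0.00863 in WT (SD, n = 3). The sense strand of intergenic spacer 2, which leads up to the 35S gene, held 0.0123% ± 0.00105 and 0.00289% ± 4.88e-04. The other strand of intergenic spacer 1 held 0.0335% ± 0.00457 and 0.0221% ± 0.00356, and the other strand of intergenic spacer 2 held 0.00606% ± 7.00e-05 and 0.00279% ± 0.00132. The sense strand of 5S held 8.22e-04% ± 2.02e-04 and 3.92e-04% ± 1.75e-04, but on only 13 and 3 counts in the mutant libraries and 3, 2 and 1 in the WT libraries. The sense strand of intergenic spacer 1 went the other way, with 0.00931% ± 4.34e-04 in the mutant and 0.0118% ± 0.00137 in WT, as did the other strand of 5S, which holds 5S rRNA itself, with 2.73% ± 0.291 and 5.32% ± 0.503. The exact permutation p was 0.2 for each of these kinds, the smallest that 10 splits can give, and the libraries did not overlap.

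Set against 1000 spacer counts of the 35S gene, taken without positions within 10 nt of a mature 3′ end, the order turned for 4 of the 5 with a larger share in the mutant. The strand opposite the 35S gene then had 8.30 ± 0.239 counts in the mutant and 14.1 ± 1.76 in WT, and the other strand of intergenic spacer 1 had 2.51 ± 0.0854 and 5.18 ± 0.833. The other strand of intergenic spacer 2 had 0.458 ± 0.0524 and 0.653 ± 0.304, and the sense strand of 5S had 0.0629 ± 0.0216 and 0.0916 ± 0.0400, and for both of these the libraries overlapped. The sense strand of intergenic spacer 2 had 0.927 ± 0.0161 in the mutant and 0.676 ± 0.105 in WT.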

How the results depend on the processing

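Chosen only after the data were seen were the scaling to spacer counts, the shares among spacer counts, the base shares and offsets from the other bases in parts of the gene, the pause caller without a count minimum, the fry tests under other scalings, the other draws of the thinning, the length left out past the mature 3′ ends among spacer counts and the background per 1000 spacer counts. Of 818 alternatives, 311 bear on values that answer a comparison. In 273 of these the result was kept, while 15 moved, 22 reversed and 1 weakened. For differences in shares, pause measures, correlations and unevenness, kept means the same direction only, whatever the size or p. For the fold change by last base it also means the same side of the threshold. A count of positions, windows or sites of 1 genotype alone was kept if it stayed within 1.5 times. Of the other 507, on single positions, windows, sets of windows and shares and ratios among spacer counts, 492 kept both, 10 reversed, 2 no longer passed and 3 passed only under the alternative. The named positions kept their call in the 231 of 240 alternatives that gave a value. The other 9, in which a position fell below the count filter, were nt 1360, 45, 6456, 556 and 496 scaled to spacer counts, nt 6456, 556 and 496 without mutant library 1, and nt 496 without the mature 3′ ends. The named windows kept it in 116 of 120. Where a value changed, the cause was not tested, except that smaller or larger windows change the number of windows. Scaled to spacer counts, 695 positions were higher and 3628 lower, and 3 windows were higher and 60 lower. Scaled to the 35S total, 1249 positions and 9 windows were lower. With 50 nt windows 56 were higher and 56 lower, and with 200 nt windows 14 and 15. In the fry tests scaled to the 35S total, the median was 0.26 for 18S and 0.14 for 25S. Scaled to spacer counts it was -0.77 for the 3′ ETS, -0.0331 for the 5′ ETS, -0.34 for ITS1, -1.12 for ITS2 and -0.0476 for the first 1000 nt, and window nt 301 to 400 was at -0.0341. The 18S share differed by -0.693 points without the mature 3′ ends and by -0.887 with the ceiling, and window nt 3001 to 3100 was at 0.22 without those ends. Among spacer counts, without the first 50 nt past the mature 3′ ends, the share differed by -2.34 points in ITS1, -1.24 in ITS2 and -0.831 in the 3′ ETS. With 0 to 100 nt left out instead, the difference ran from -2.64 to 0.262 in ITS1, reversed only with none left out, from -12.2 to -0.574 in ITS2, from -4.51 to -0.0141 in the 3′ ETS and from 3.28 to 16.4 in the 5′ ETS. The pause count differed by -0.833 at 4 SD, by 0 with 200 nt on each side and by -40.5 with the median absolute deviation. The sites of the mutant alone were 117 at 2 SD and 23 at 4 SD, and those of WT alone 108 and 21. The share of pause sites at C differed by 0.536 points without the mature 3′ ends, 0.00437 with the ceiling and 1.73 at 2 SD, by 0.0585 on average over the other draws, and by -1.38 to 0.363 when each library was left out in turn. The share of signal at A differed by 0.893 in the 5′ ETS and 0.0249 in all spacers, and that at C by -3.07 without the mature 3′ ends, -3.28 with the ceiling, -4.73 in the 5′ ETS, -3.89 in all spacers and -2.87 in 18S and 25S. The log2 fold change at A minus the other bases was 0.0768 when the base 1 nt downstream was read and -0.28 in the 5′ ETS (adjusted p = 0.0789, permutation by circular shifts), and that at C was 0.14 and 0.17 for the base 1 nt upstream and downstream, which are different quantities. G minus the other bases stayed between 1.78 and 1.95 when each library was left out. With the replicate block, 2098 positions were higher and 1911 lower, and 25 windows were higher and 21 lower. Only 2 numbers are shared by the genotypes and deviations correlated by 0.0127 and 0.0163 between libraries of the same number, so the numbers were not taken to pair the samples. With a group left at 1 library no permutation test was made. The spread in the fits of positions and windows then came from the WT libraries alone, so calls kept there carry less weight. Each rDNA repeat alone was not run, because the files hold 1 repeat.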

Other observations

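In this part, the tests of G upstream, of carryover, of depth and of a single mutant library were chosen only after the result was seen, as were the short stretches beside processing sites. In 3 such stretches RNA 3′ ends took a smaller share in the mutant. Ends within 8 nt past the 5.8S 3′ end (nt 3020 to 3027) held 0.887% ± 0.0644 of the sense 35S signal in WT (SD, n = 3) and 0.221% ± 0.0109 in the mutant (SD, n = 2). Ends at A2 (nt 2710 to 2712) held 0.0274% ± 0.00729 and 0.00648% ± 0.00210, and ends at nt 6655 to 6662 in the 3′ ETS held 0.114% ± 0.0137 and 0.0160% ± 0.00137. Just past these, nt 6663 to 6697, the stretch removed by the endonuclease Rnt1, held 0.257% ± 0.0238 in the mutant and 0.0504% ± 0.00387 in WT, 5.11 times as much. The terminator position T1 (nt 6739) held 0.00117% ± 2.46e-04 in the mutant (25 and 3 counts) and 0.00689% ± 0.00134 in WT. The mature 3′ ends themselves also took a smaller share in the mutant. Relative to the 5.8S 3′ end, the log2 ratio of ends at nt 3020 to 3027 differed by only -0.618, mutant minus WT. Relative to the 25S 3′ end, that of ends at nt 6655 to 6662 differed by -1.63. Within 25 nt of the cleavage sites the mutant counts went both ways, at 1.20 to 3.09 times the WT share around A0, A1, A2, C2 and the 5′ ends of 5.8S and 25S, and at 0.407 to 0.630 times around the 3′ ends of 18S, 5.8S and 25S. Around A0 and A2 the rise was smaller than in the whole 5′ ETS and the whole ITS1.

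The share of 3′ ends in the 5′ ETS was 3.27 times as high in the mutant. Fewer mature rRNA ends would raise all spacers alike, and the log2 ratio of 5′ ETS to 3′ ETS counts does not decide on this as the whole cause: it was higher by 0.877 with the first 50 nt past the 25S 3′ end left out, but by 0.0798 to 1.55 with 0 to 100 nt left out instead. Less carryover could account for the part shared with ITS1. The log2 ratio of 5′ ETS to ITS1 counts rose by only 0.326 (0.294 to 0.402 with the other lengths), while the log2 share of the 5′ ETS rose by 1.70. Fewer mature rRNA ends alone, as the whole cause, are argued against by the same ratio. It was higher in each mutant library than in every WT library at each length, by at least 0.277 with 50 nt left out. The ratio does not decide on carryover of precursors, whose ends lie in ITS1 too. Those at A2 also took a smaller share in the mutant. A few very high positions and depth are argued against, since the difference was 5.86 percentage points with the ceiling, and the shallower mutant library lay 5.90 points above the highest WT library. A slower passage of the mutant polymerase through the start of the gene may account for a part and stays untested, as does a batch that the labels do not give.

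The higher share of signal at G was the other pattern weighed. A change in library preparation that favours G at every RNA 3′ end is argued against by 5S, where the log2 odds of G rose by 0.197 against 1.86 over the 35S gene, although 5S ends come from finished or broken RNA. In that part of 5S, 29 of 115 positions are G, and the WT share at G given above was already close to this. So 5S could hardly show a change that only moves ends toward the base composition, and such a change was not tested. Less carryover is argued against by the 5′ ETS, where the log2 odds rose by 1.49, and a few high positions by the rise of 1.70 without the highest 1% of positions. Both mutant libraries showed it, the lower lying 12.9 percentage points above the highest WT library. G makes up 26.3% of the gene, and the share of signal at G was below this in both genotypes. The pattern is therefore a weaker depletion of G than in WT, not an excess. Of the 55 pause sites of the mutant alone, 7 ended in G and 32 in U, against none in G among the 42 of WT alone. A slower step after G is added by the mutant polymerase is a candidate explanation that was not tested. Genotype cannot be told apart from an unlabelled batch that acts on polymerase I RNA alone, and the sample names inside the mutant files leave the genotype to the labels.

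The bases before the 3′ end went with the fold change as well. Among 4414 positions that end in A, C or U, the log2 fold change rose by 0.456 per G in the 8 nt before (p = 0.001, the smallest that 1000 circular shifts can give in this permutation), so that the last base alone could not account for it. The mean was -1.06 with no G in those 8 nt and 0.89 with 5. In the 5′ ETS the slope was 0.350 (permutation p = 0.001). Over all tested positions, G minus the other bases was also 0.32 at 9 nt and 0.21 at 12 nt before the 3′ end. It was 0.31 at 1 nt after that end, so the difference was not confined to these 8 nt. As hypotheses only, pairing of G in the RNA with the DNA template, or with RNA folded behind the polymerase, may play a part. Neither was tested, and an unlabelled batch cannot be told apart from them.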
